A study of Mus musculus with 4 samples.

How the data were processed

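The 4 libraries are droplet single-cell libraries of SB28 tumours from mice given an antisense oligonucleotide (ASO) against Trem2 or an inactive ASO, with 2 libraries per group. Per the labels, libraries were made with the 10x Genomics Single Cell 3' v3 kit, after CD45 bead enrichment of dissociated tumours, and hold CD45-positive and CD45-negative cells. The deposited values are raw UMI counts per gene and barcode over all barcodes, empty droplets included. They are not normalised, and hold 32285 genes and 1986084 to 2503659 barcodes per library. Per the submitters' processing notes the counts came from Cell Ranger 7.0.1 on build mm10, whereas the file headers name version 4. Neither source states the annotation or whether intronic reads were counted. Strand and near-identical gene copies were handled upstream and could not be re-examined.

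Cells were called from the deposited counts as barcodes with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. The cells with the highest Scrublet scores (scanpy 1.11.5) were removed at 0.8% per 1000 cells of each library, a rate set before the data were examined, 2908 cells in all. The threshold that Scrublet sets itself called 3 cells, too few to have worked, and was not used. This left 7565, 8080, 8678 and 10530 cells in Trem2 ASO 1, Trem2 ASO 2, inactive ASO 1 and inactive ASO 2, with median UMI counts of 14768, 12629, 14200 and 12001. Counts were scaled to 10000 per cell and log-transformed. Leiden clustering used 2000 variable genes, 30 principal components, 15 neighbours and resolution 1.0, with Trem2, sex-linked, mitochondrial, ribosomal and receptor variable genes left out and no integration across libraries.

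The 36 clusters were named from marker lists fixed before the data were examined. A cluster took a name when its marker score was at least 0.5, at least 3 markers of that type were detected (20 CPM and 5% of cells), and its 10 leading genes held no more markers of another type than of its own. Clusters with few UMIs and no marker among those genes stayed unnamed. Names mean that a cluster is macrophage-like, microglia-like and so on, and the suffix is dropped hereafter. Of the clusters, 28 were named and 8 stayed unnamed, with 6753 cells. Clusters 22 and 30 were kept unnamed by a rule set after the clusters were seen, since genes of plasma cells (Jchain, Mzb1) and of eosinophils (Ccr3, Alox15) led them. Red-cell markers were left out of the naming, also after the clusters were seen. T cells were clustered again with 1000 variable genes and 20 components to name T cell subsets.

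For each class, raw UMI counts were summed per library, so that n = 2 libraries per group. The sums were tested with edgeR 4.0.16 (TMM normalisation, filterByExpr, quasi-likelihood test, group alone in the model) in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that class. Levels are TMM-normalised CPM. A class needed 20 cells in every library. Whether an effect differed between macrophages and microglia was tested as a class-by-treatment interaction with the library as a block. Shares of classes were compared with an exact two-sided permutation test over the 6 assignments of libraries to groups, whose smallest p is 0.333, so no share can reach 0.05.

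For each class, 25 gene lists fixed before the data were examined were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. In these 2 tests 0 lists passed in any class, and the model leaves few residual degrees of freedom. Marker lists of other cell types were tested in the same way as a separate family.

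The genes named were chosen by a rule fixed before the data were examined. In macrophages, monocytes, microglia and T cells it takes up to 10 higher and 10 lower called genes with the smallest adjusted p and with libraries that did not overlap between groups. Where fewer passed it adds up to 3 per direction that did not pass. It also takes Trem2 in each class, up to 4 members with the smallest p of each list described, Pdcd1, Cd8a, Cd4, Foxp3, Gzmb and Ifng in T cells, sex-linked genes, and up to 3 called genes per direction in other classes. Gene positions came from GENCODE M21 on GRCm38, in which 32158 of the 32285 gene identifiers were found.

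The tests were run first on simulated counts with known changes, drawn from the means and totals of each class. In simulated macrophages edgeR recovered 40% of genes changed 1.5-fold and 64% of those changed 2-fold, among 14931 genes tested. In simulated monocytes these shares were 32% and 74%, in microglia 12% and 60%, and in T cells 44% and 82%. False calls numbered 19, 30, 15 and 17. In macrophages they stood beside 20, 32, 42 and 44 recovered genes at 1.5, 2, 3 and 4-fold. In monocytes they stood beside 16, 37, 46 and 49. In each class false calls were a larger share of all calls than the adjusted p threshold is set to allow, so some called genes may be false. The interaction recovered 2% at 1.5-fold and 38% at 2-fold, with 11 false calls.

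Free RNA was profiled in barcodes of 10 to 100 UMIs and scaled by markers of other cell types with at least 20 UMIs. It made up 2.28% to 4.28% of UMIs in macrophages, monocytes and microglia. In T cells this scaling gave 110% in 1 library, which cannot be. A second scaling, chosen after seeing the data, used markers with at least 5 UMIs and left out neutrophil and B cell markers in T cells. It gave 1.81%, 2.56%, 5.53% and 4.26% in T cells of Trem2 ASO 1, Trem2 ASO 2, inactive ASO 1 and inactive ASO 2.

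Other alternatives were DESeq2 1.42.0, edgeR's median-of-ratios factors, no filter on low counts, the replicate number as a block, each library left out, at least 1000 UMIs and 500 genes per cell, a per-library cell minimum, up to 20% mitochondrial UMIs, no doublet removal and Leiden resolutions of 0.5 and 2.0. T cells without mixed profiles, meaning over 0.3% neutrophil genes or over 1% macrophage genes, were added after seeing the data. So were shares over all clusters with at least 100 CPM of Ptprc, and T subsets as shares of named subsets. Xist stood at 426 to 509 CPM in macrophages of the 4 libraries and the Y-linked Ddx3y at 2.04 to 3.03 CPM, and Eif2s3y and Kdm5d had no UMI there. Libraries of a group were checked for duplication, and in macrophages the chi-square per degree of freedom between them was 4.42 under the Trem2 ASO label and 60.2 under the inactive ASO label.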

Results

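Single-cell transcriptomes were measured in SB28 glioblastoma, a mouse glioma cell line grown in the brain. Mice received 1 intracerebroventricular injection of an ASO against Trem2, a lipid-sensing receptor of myeloid cells, or of an inactive ASO. Per the labels the dose was 400 µg, with 401 µg written for Trem2 ASO 2. Then 7 days later, 8000 SB28 cells were injected, and tumours were taken after a further 30 days. The design names 5 mice injected per group and 2 libraries per group, and the labels do not say whether a library is 1 mouse. The libraries Trem2 ASO 1, Trem2 ASO 2, inactive ASO 1 and inactive ASO 2 held 188238669, 170020177, 218640294 and 223029148 UMIs. In all, 34853 cells were analysed, of which 23855 fell into named immune classes.

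The targeted gene was examined first, as a check of the labels. Trem2 (ENSMUSG00000023992, GRCm38 chromosome 17, 48346401 to 48354147) was not lower in the libraries labelled Trem2 ASO in macrophages, monocytes or microglia. In macrophages it stood at 507 ± 12.0 CPM (SD, n = 2) in the libraries labelled Trem2 ASO and 395 ± 57.6 in those labelled inactive ASO, a log2 fold change of 0.36 ± 0.11 (SE, edgeR adjusted p = 0.196). In monocytes it stood at 309 ± 3.75 against 209 ± 0.0378 CPM, a log2 fold change of 0.56 ± 0.07 (edgeR adjusted p = 0.0572). In microglia, where Trem2 was most abundant, it stood at 1096 ± 83.0 against 1060 ± 141 CPM, a log2 fold change of 0.05 ± 0.12 (edgeR adjusted p = 0.926). The libraries of the groups did not overlap in macrophages and monocytes, and did in microglia. Of all genes tested, 56.4% in macrophages and 50.1% in monocytes showed no overlap, against 33.3% by chance, so this adds little. Fibroblast-like cells held 9.72 ± 1.95 against 12.3 ± 0.260 CPM of Trem2. Other immune classes held more, at 120 against 95.1 CPM in neutrophils, 128 against 113 in T cells and 174 against 145 in B cells. NK cells, at 27.0 against 25.2 CPM, and conventional dendritic cells, at 34.9 against 25.6, lay lower. Whether Trem2 in these classes came from other cells was not tested, so the fibroblast-like level is not a background for monocytes. Oligodendrocytes held 34.1 ± 6.26 against 66.6 ± 11.2 CPM, lower without overlap (log2 fold change −0.95 ± 0.39, edgeR adjusted p = 0.796). Their cluster 32 held the immune gene Ptprc at 285 CPM. Log2 fold changes were 0.33 in neutrophils, 0.18 in T cells, 0.24 in B cells, 0.10 in NK cells, 0.54 in conventional dendritic cells and 0.52 in tumour or glial progenitor cells, and none passed.

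In macrophages the log2 fold change of Trem2 was 0.22 without inactive ASO 1 and 0.53 without inactive ASO 2. In monocytes it was 0.56 without inactive ASO 1 and 0.57 without inactive ASO 2. In microglia it fell below 0 without Trem2 ASO 2 (−0.03) or inactive ASO 1 (−0.08). Without an inactive ASO library the spread comes from the close pair labelled Trem2 ASO alone, so whether Trem2 passes there decides nothing. With all libraries Trem2 was higher under the Trem2 ASO label in macrophages and monocytes, against the label, but did not pass. Every direction given here is therefore that of the library labelled Trem2 ASO over the library labelled inactive ASO. It is not a measured effect of lower Trem2. The labels do not state how the ASO acts, and counts of 3' tags would not show a block of translation.

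**Figure D1:**
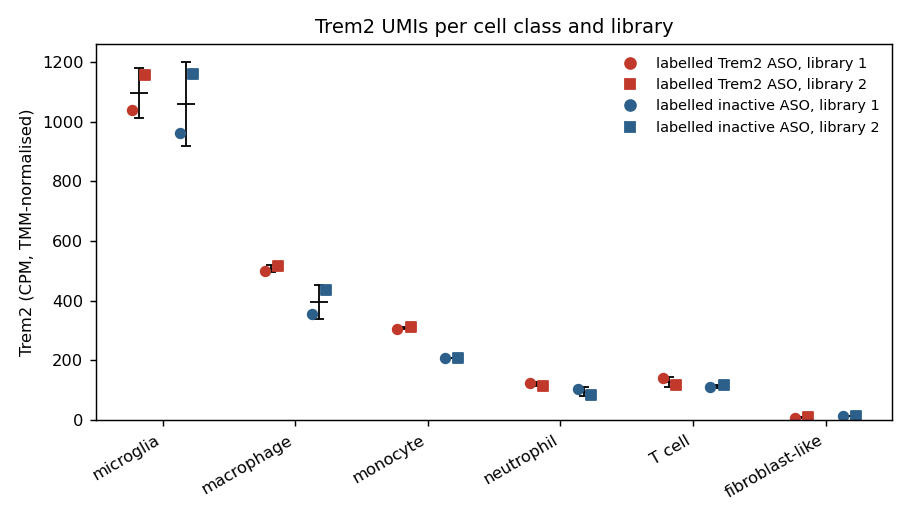
Trem2 in TMM-normalised CPM (vertical axis) in 6 cell classes (horizontal axis). Each point is 1 library, and black bars show the mean and SD of the 2 libraries of a group. In macrophages the libraries labelled Trem2 ASO stood at 499 and 516 CPM, above those labelled inactive ASO at 354 and 435 CPM.

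Neutrophils made up a larger share of named immune cells in the libraries labelled Trem2 ASO, and monocytes and microglia a smaller one. Neutrophils were 13.5% ± 0.201 (SD, n = 2) of named immune cells under the Trem2 ASO label and 9.19% ± 1.81 under the inactive ASO label. Monocytes were 16.9% ± 0.433 against 21.9% ± 0.430, and microglia 9.50% ± 0.280 against 13.5% ± 2.70. Macrophages, the most frequent class, were 48.5% ± 0.644 against 44.7% ± 3.00. In these 4 classes the libraries of the groups did not overlap, and each exact permutation p was 0.333, the smallest that 6 assignments allow. Macrophages and monocytes overlapped with at least 1000 UMIs per cell (differences of 0.939 and −3.74 percentage points) and with a per-library cell minimum (0.157 and −0.902), and macrophages also without doublet removal. The macrophage difference of 3.76 points became 5.89 without inactive ASO 1 and 1.64 without inactive ASO 2, and the microglia difference of −4.02 became −2.11 without inactive ASO 1. T cells were 8.23% ± 0.414 against 6.81% ± 1.82, with overlapping libraries (exact permutation p = 0.667). NK cells were 0.945% ± 0.186 against 0.726% ± 0.0437 without overlap (exact permutation p = 0.333), but overlapped at Leiden resolution 2.0, with a per-library cell minimum and without doublet removal. B cells, at 1.08% ± 0.0516 against 1.85% ± 1.11, and conventional dendritic cells, at 1.29% ± 0.222 against 1.11% ± 0.440, overlapped. CD45 bead enrichment sets the ratio of immune to other cells. Unnamed cluster 4, whose best markers are those of macrophages, is in no class. It held 7.22% ± 0.725 against 7.12% ± 0.310 of all cells. The conventional dendritic cell class is cluster 23 alone, with 292 cells. Unnamed cluster 14, with 871 cells, also scored best for that type and is in no class. It held 2.34% ± 0.189 against 2.54% ± 1.29 of all cells.

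**Figure D2:**
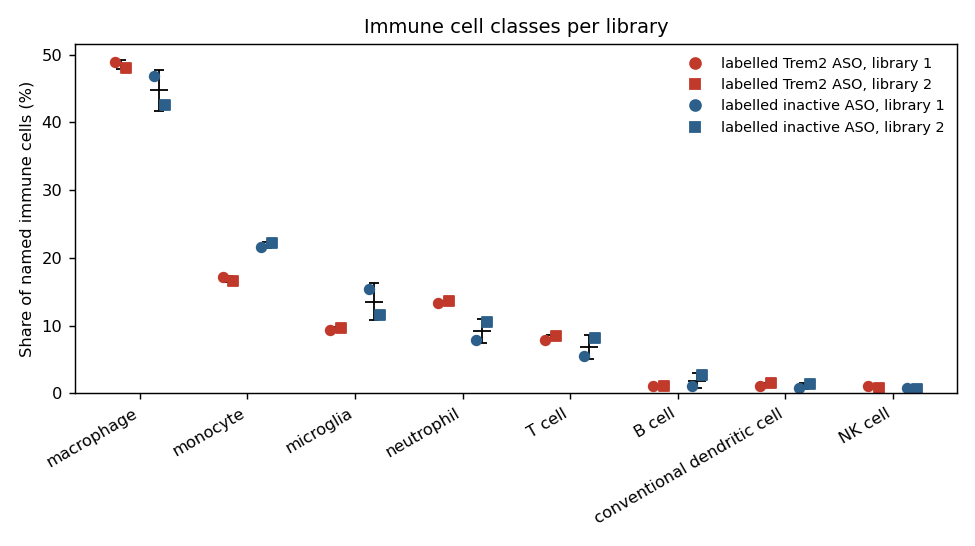
Share of each class among named immune cells, in percent (vertical axis), for 8 immune classes (horizontal axis). Each point is 1 library, and black bars show the mean and SD of the 2 libraries of a group. Monocytes of the libraries labelled Trem2 ASO stood at 17.2% and 16.6%, below 21.6% and 22.2% in those labelled inactive ASO.

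In macrophages, 17 genes rose and 6 fell in the libraries labelled Trem2 ASO, among 15133 tested with edgeR. Cd163 (ENSMUSG00000008845), the scavenger receptor for haptoglobin and haemoglobin, rose from 0.822 ± 0.058 to 12.3 ± 1.17 CPM (SD, n = 2), a log2 fold change of 3.91 ± 0.16 (SE, edgeR adjusted p = 0.00569). Ccl24 (ENSMUSG00000004814), the chemokine eotaxin-2, rose from 5.97 ± 2.35 to 95.8 ± 10.7 CPM (log2 fold change 4.01 ± 0.26, edgeR adjusted p = 0.0221), and the monocyte-attracting chemokine Ccl8 from 61.4 ± 3.44 to 256 ± 46.5 CPM (2.06 ± 0.14). The histone deacetylase gene Hdac9 (1.01), the carbonyl reductase gene Cbr2 (1.40), Ms4a8a (1.29), Gm17268 (1.12), the GDP-fucose synthesis gene Tsta3 (0.86), the schlafen gene Slfn4 (0.93) and the chemokine Ccl9 (0.98) also rose. Among the genes that fell were Slc7a11, the cystine and glutamate exchanger (−1.02), Pmvk of the mevalonate pathway (−1.06), Abcb1a, the drug efflux pump (−1.27), the serotonin receptor gene Htr7 (−0.78), the cold-inducible Cirbp (−0.92) and Rundc3b (−1.26). Cdh23 (−0.92), Adgrg5 (−1.40) and the integrin gene Itgax (−0.89) had the smallest p among lower genes that did not pass, each at an edgeR adjusted p of 0.0564.

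**Figure D3:**
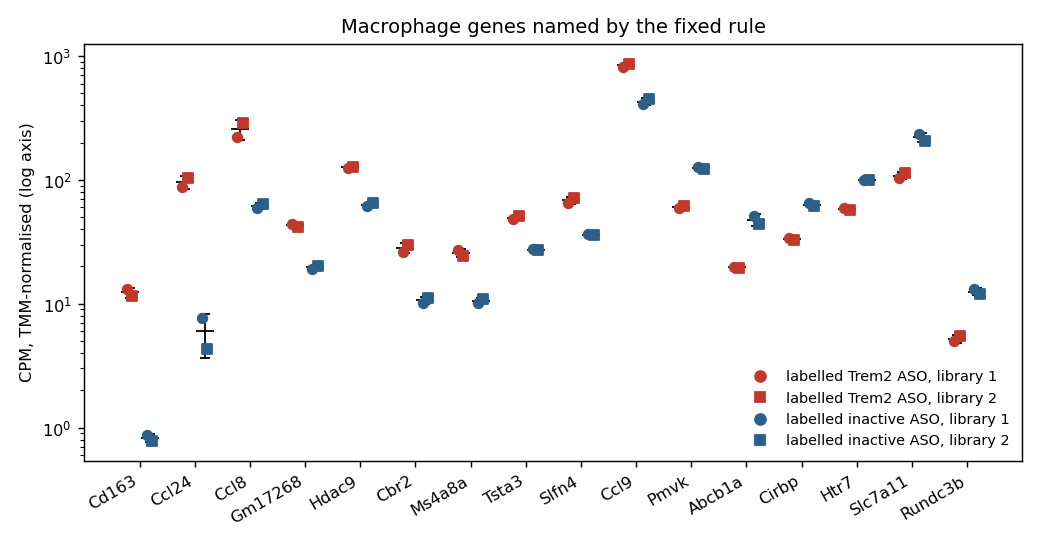
TMM-normalised CPM in macrophages (vertical axis, log scale) of the 16 called genes named by the rule (horizontal axis). Each point is 1 library, and black bars show the mean and SD of the 2 libraries of a group. The libraries of the groups do not overlap for any of these genes, since the rule asked for that.

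Of the 25 gene lists, 9 rose in macrophages under the Trem2 ASO label by limma camera. In the anti-inflammatory or tissue-repair list 13 of 19 measured members were higher (median log2 fold change 0.36, limma camera adjusted p = 3.7e-15, adjusted p = 0.263 with an estimated correlation). Cd163, Ccl24 and Ccl8 passed over all genes, 6 members rose when adjusted over the list alone, and Folr2, a folate receptor, stood at 24.0 against 8.60 CPM. In the type I interferon response 19 of 20 members were higher (median 0.27, limma camera adjusted p = 1.12e-09, adjusted p = 0.263 with an estimated correlation). The nucleic acid sensor Zbp1 (0.74) passed over all genes and 10 members adjusted over the list alone, with Isg15 at 334 against 214 CPM, Ifit3 at 62.1 against 41.2 and Oasl2 at 104 against 78.7. Of the leukocyte-attracting chemokines 6 of 11 were higher (median 0.16, limma camera adjusted p = 6.57e-05, adjusted p = 0.355 with an estimated correlation). Ccl8 passed over all genes, 4 rose and 1 fell adjusted over the list alone, and Ccl2 stood at 751 against 434 CPM and Ccl7 at 485 against 252.

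Oxidative phosphorylation (30 of 34 members higher, 0 called adjusted over the list alone, limma camera adjusted p = 0.000543) and complement (10 of 11, 4 called adjusted over the list alone; 0.00337) also rose in macrophages, both at adjusted p = 0.621 with an estimated correlation. So did dissociation stress genes (15 of 21, 8 rose and 1 fell adjusted over the list alone, limma camera adjusted p = 0.00434, adjusted p = 0.445 with an estimated correlation) and the cell cycle (25 of 27, 0 called adjusted over the list alone; 0.00434, adjusted p = 0.788 with an estimated correlation). The interferon-gamma response (16 of 19, 2 rose and 1 fell adjusted over the list alone, limma camera adjusted p = 0.0196, adjusted p = 0.621 with an estimated correlation) and homeostatic microglia genes (16 of 20, 2 rose and 1 fell adjusted over the list alone; 0.0356, adjusted p = 0.788 with an estimated correlation) passed as well. Within the interferon-gamma list the checkpoint ligand gene Cd274 stood at 139 against 201 CPM (edgeR adjusted p = 0.0774). Microglia markers (9 of 10 higher, median 0.24, limma camera adjusted p = 0.0211) and monocyte markers (6 of 10, median 0.23; 0.0451) rose beside these lists, both at adjusted p = 0.927 with an estimated correlation. The Trem2-dependent disease-associated list did not pass (13 of 24 higher, limma camera adjusted p = 0.882), nor did MHC class II (2 of 9; 0.183), phagocytic receptors (14 of 18; 0.0616) and lysosome (15 of 30; 0.631).

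The macrophage class was made of different clusters in different libraries. Cluster 5 (Gpnmb, Chil3) held 56.8% of macrophages in inactive ASO 1, against 9.43%, 10.1% and 15% in Trem2 ASO 1, Trem2 ASO 2 and inactive ASO 2. Cluster 1 (Pf4, Mrc1) held 34.8%, 34.2%, 8.49% and 20.2% in Trem2 ASO 1, Trem2 ASO 2, inactive ASO 1 and inactive ASO 2, and cluster 0 held 32.2%, 33.0%, 17.3% and 45.1%. Ccl8, Ccl24, Ccl7 and Ccl9 were among the leading genes of cluster 1. Ccl24 and Ccl8 rose by a larger factor than the share of that cluster did, whereas the higher values of Ccl9, Ccl7 and the tissue-repair list as a whole were not separated from it. Cluster 17, led by interferon-induced genes such as Ifit3, Rsad2 and Isg15, held 7.12%, 8.26%, 3.60% and 3.42%, and the rise of the type I interferon list was not separated from that share either. The count of 23 called genes became 17 without Trem2 ASO 1, 15 without Trem2 ASO 2, 2891 without inactive ASO 1 and 6606 without inactive ASO 2. Of the 16 called genes named above, 8 kept their call with each library left out (Cd163, Ccl24, Ccl8, Gm17268, Hdac9, Cbr2, Ms4a8a, Abcb1a), whereas Cd163 alone kept it without doublet removal and Cd163 and Ccl24 with at least 1000 UMIs per cell. Fits without an inactive ASO library take their spread from the close pair labelled Trem2 ASO alone, so calls kept there decide little. The naming rule had also asked for no overlap between the groups. The type I interferon, interferon-gamma and cell cycle lists turned to lower at Leiden resolution 2.0 (limma camera adjusted p = 0.949, 0.204 and 0.0737). Of the 9 lists, only 3 kept their call at that resolution.

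In monocytes, 4 genes rose and 5 fell in the libraries labelled Trem2 ASO, among 12352 tested with edgeR. Ccl24 rose from 15.4 ± 5.01 to 144 ± 45.7 CPM (SD, n = 2), a log2 fold change of 3.21 ± 0.27 (SE, edgeR adjusted p = 0.0283), and Tsta3 from 21.3 ± 2.21 to 42.5 ± 0.149 CPM (0.996 ± 0.10). The calcium channel subunit gene Tmem37 (0.70) and the cyclin-dependent kinase gene Cdk11b (0.65) also rose. The interferon-induced membrane protein gene Ifitm6 fell from 85.2 ± 1.70 to 46.3 ± 0.376 CPM (−0.88 ± 0.07, edgeR adjusted p = 0.0283), and the sorting receptor gene Sorl1 (−0.80), Abcb1a (−0.99), Ston2 (−0.70) and Themis2 (−0.72) fell as well. Among genes that did not pass, caveolin Cav1 stood at 13.1 against 4.95 CPM, the neutrophil-attracting chemokine Cxcl1 at 37.3 against 11.0, Gabbr2 at 4.74 against 11.3 and the Notch target Hes1 at 17.9 against 31.9.

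Of the 25 lists, 4 rose and 4 fell in monocytes by limma camera, and each had an adjusted p = 0.561 with an estimated correlation. The anti-inflammatory or tissue-repair list rose (12 of 17 higher, median 0.35, limma camera adjusted p = 2.42e-07), with Ccl24 passing over all genes and 8 rising and 1 falling adjusted over the list alone. Its member Mrc1, the mannose receptor, stood at 317 against 138 CPM. Cholesterol biosynthesis rose (18 of 20, 2 adjusted over the list alone; 0.000936), with mevalonate kinase Mvk at 9.72 against 5.59 CPM, as did oxidative phosphorylation (29 of 34, 0 adjusted over the list alone; 0.000936) and complement (8 of 11, 3 adjusted over the list alone; 0.0439). The type I interferon response fell (18 of 20 lower, median −0.25, 3 adjusted over the list alone, limma camera adjusted p = 2.52e-05), with Ifit2 at 165 against 227 CPM and Ifi27l2a at 1839 against 2467. The interferon-gamma response fell (17 of 19 lower, 0 adjusted over the list alone; 0.00192), with Irgm1 at 82.8 against 110 CPM, and so did the pro-inflammatory list (13 of 18, 1 adjusted over the list alone; 0.0439), with nitric oxide synthase Nos2 at 47.6 against 75.1. The interferon-gamma, pro-inflammatory, cholesterol biosynthesis and complement lists did not keep their calls with each library left out. The naive or memory T list fell (6 of 8, 3 adjusted over the list alone; 0.00515), a list whose members are also expressed outside T cells. The Trem2-dependent disease-associated list did not pass (15 of 23 higher, limma camera adjusted p = 0.19), nor did MHC class II (0 of 9 higher; 0.221).

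Macrophage markers (8 of 10 higher, median 0.29, limma camera adjusted p = 0.00554) and microglia markers (7 of 8; 0.0426) rose and red-cell markers fell (5 of 5 lower; 0.0201) beside these lists in monocytes, each at adjusted p = 0.504 with an estimated correlation. Cluster 2, led by Ly6c2 and interferon genes, held 75.0% of monocytes in inactive ASO 1 and 48.6%, 49.0% and 49.7% in Trem2 ASO 1, Trem2 ASO 2 and inactive ASO 2. Cluster 7, with Ccl24 and Arg1 among its leading genes, held 47.6%, 45.9%, 20.5% and 42.2% in Trem2 ASO 1, Trem2 ASO 2, inactive ASO 1 and inactive ASO 2. Ccl24 rose by a larger factor than that share, whereas the rise of the tissue-repair list was not separated from it. The count of 9 called genes became 1 without Trem2 ASO 1, 2 without Trem2 ASO 2, 1539 without inactive ASO 1, 2278 without inactive ASO 2 and 0 at Leiden resolution 2.0, and Ccl24 alone kept its call with each library left out. As in macrophages, calls kept without an inactive ASO library decide little. Whether the opposite directions of the interferon lists in macrophages and monocytes differ was not tested.

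In microglia no gene passed, among 11986 tested with edgeR, of which 1004 had an unadjusted p under 0.05, and DESeq2 called 24. Cluster 10, with a median of only 1640 UMIs per cell, held 48.0%, 44.9%, 53.0% and 44.6% of microglia in Trem2 ASO 1, Trem2 ASO 2, inactive ASO 1 and inactive ASO 2. Cluster 12 had a median of 17186 UMIs. Cells of cluster 10 thus weigh little in the summed counts, but count in full in the share of microglia. The adhesion molecule gene Alcam stood at 129 ± 18.7 CPM (SD, n = 2) in the libraries labelled Trem2 ASO and 49.0 ± 3.33 in those labelled inactive ASO (log2 fold change 1.39 ± 0.14, SE, edgeR adjusted p = 0.125). Slfn4 stood at 30.7 against 9.16 CPM, the neutrophil-attracting chemokine Cxcl3 at 106 against 30.0, Cirbp at 35.9 against 63.9 and Gm12865 at 18.4 against 36.2. By limma camera 7 of 25 lists rose. Dissociation stress genes rose (20 of 21 higher, median 0.33, 2 adjusted over the list alone, limma camera adjusted p = 4.25e-08, adjusted p = 0.59 with an estimated correlation), with Jun at 651 against 451 CPM and the heat shock gene Hsph1 at 19.1 against 10.3. The type I interferon response rose (18 of 20, 1 adjusted over the list alone, limma camera adjusted p = 0.000228, adjusted p = 0.59 with an estimated correlation), with Rsad2 at 140 against 94.7 CPM. Glycolysis (13 of 15, 0 adjusted over the list alone, limma camera adjusted p = 0.00208, adjusted p = 0.832 with an estimated correlation) and oxidative phosphorylation (30 of 34, 0 adjusted over the list alone; 0.00208, adjusted p = 0.59 with an estimated correlation) rose too.

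Homeostatic microglia genes rose in microglia (17 of 20, 0 adjusted over the list alone, limma camera adjusted p = 0.00749, adjusted p = 0.883 with an estimated correlation), and turned to lower without inactive ASO 1 (0.484). The anti-inflammatory or tissue-repair list rose (11 of 17, 4 adjusted over the list alone, limma camera adjusted p = 0.0251, adjusted p = 0.59 with an estimated correlation), with arginase Arg1 at 293 against 138 CPM, and so did complement (7 of 11, 1 adjusted over the list alone; 0.0495, adjusted p = 0.791 with an estimated correlation). The Trem2-dependent disease-associated list did not pass (13 of 24 higher, limma camera adjusted p = 0.962). Neutrophil markers rose in the same cells (7 of 8, median 1.25, limma camera adjusted p = 3.04e-09), as did monocyte (8 of 9, median 0.40; 0.00132), endothelial (3 of 3; 0.0015) and plasmacytoid dendritic cell markers (5 of 5; 0.0095), and red-cell markers fell (4 of 4 lower, median −2.15; 0.00132). With an estimated correlation the adjusted p was 0.402 for neutrophil and endothelial markers and 0.46 for the others. The count of 0 called genes became 21 without Trem2 ASO 2, 223 without inactive ASO 1 and 1386 without inactive ASO 2.

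In T cells, 22 genes rose and 7 fell in the libraries labelled Trem2 ASO, among 13324 tested with edgeR. The proliferation gene Pclaf rose from 29.8 ± 1.64 to 72.8 ± 6.57 CPM (SD, n = 2), a log2 fold change of 1.296 ± 0.11 (SE, edgeR adjusted p = 0.0187), and the growth factor gene Areg from 149 ± 9.85 to 296 ± 30.3 CPM (0.99 ± 0.10, edgeR adjusted p = 0.0331). Trgv2, a gamma-chain segment of the T cell receptor (1.75), Gm42047 (1.64), Dscaml1 (4.44) and Fam71f2 (1.16) rose as well. Genes abundant in neutrophils rose beside them, among them the collagenase gene Mmp8 (22.1 ± 2.00 to 56.3 ± 1.83 CPM), the lipocalin gene Lcn2 (22.5 ± 4.73 to 72.6 ± 0.0351 CPM), Cstdc4 (1.70) and Csta2 (2.11), which belong to a family of similar copies. The granzyme gene Gzmf, from a cluster of similar granzyme genes, fell from 3665 ± 1258 to 966 ± 86.8 CPM (−1.92 ± 0.22, edgeR adjusted p = 0.0389). Mgp (−2.77), Adamtsl1 (−4.85), Cirbp (−0.78), Ssbp2 (−0.75), Gm2682 (−0.86) and Spon1 (−0.74) also fell. Mgp is a leading gene of fibroblast-like cluster 3. Fibroblast-like cells were 18.9% of all cells in inactive ASO 1 and 8.97% in inactive ASO 2. They were 8.88% and 8.08% under the Trem2 ASO label. Whether RNA of these cells gave the fall of Mgp was not tested. With genes of high free RNA left out by the added scaling, 24 genes rose and 5 fell, 27 of them among the calls above. Of the 17 called genes named, only 15 were still tested there, and each of these kept its call.

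Regulatory T cells made up 26.9% ± 0.604 (SD, n = 2) of the T cell class in the libraries labelled Trem2 ASO and 15.8% ± 1.96 in those labelled inactive ASO, without overlap (exact permutation p = 0.333, the smallest possible). CD8 T cells made up 17.6% ± 3.39 against 20.5% ± 10.8 with overlap (exact permutation p = 1), and sub-clusters left unnamed 48.7% ± 2.84 against 56.0% ± 7.20. Regulatory T sub-cluster 6, led by Mki67 and Top2a, held 40, 46, 12 and 21 of the 435, 513, 285 and 583 T cells in Trem2 ASO 1, Trem2 ASO 2, inactive ASO 1 and inactive ASO 2, and the rise of cell cycle genes in the class was not separated from its share. As shares of named subsets, regulatory T cells were 49.6% and 55.3% against 29.3% and 44.1%. In the whole T cell class Foxp3, which specifies regulatory T cells, stood at 51.3 against 44.2 CPM (edgeR adjusted p = 0.353), and with a per-library cell minimum its log2 fold change was −0.04. Cd8a (109 against 84.2 CPM, edgeR adjusted p = 0.133), Cd4 (39.5 against 46.7), Pdcd1 (88.4 against 98.3), Gzmb (404 against 439) and Ifng (60.3 against 77.7) did not pass either. Pdcd1 and Ifng turned to higher without inactive ASO 1 (log2 fold changes 0.09 and 0.93), and Gzmb without Trem2 ASO 1 (0.0046).

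Of the 25 lists, 12 rose and 4 fell in T cells by limma camera. The cell cycle rose (27 of 27 higher, median 0.64, limma camera adjusted p = 7.28e-24, adjusted p = 0.181 with an estimated correlation), with topoisomerase Top2a (0.73) and Stmn1 (1.09) passing over all genes and 23 members adjusted over the list alone. Glycolysis (15 of 15, 10 adjusted over the list alone, limma camera adjusted p = 6.15e-07) and hypoxia (11 of 15, 4 adjusted over the list alone; 6.83e-05) rose, both at adjusted p = 0.367 with an estimated correlation, with Ero1l (0.75) passing over all genes. Cholesterol biosynthesis rose (16 of 20, 3 adjusted over the list alone, limma camera adjusted p = 0.000261, adjusted p = 0.421 with an estimated correlation). Exhaustion genes rose (9 of 13, 3 adjusted over the list alone, limma camera adjusted p = 0.00159), with the regulator Tox at 394 against 252 CPM and the receptor Lag3 at 43.3 against 31.3, as did cytotoxic effectors (11 of 18, 10 rose and 2 fell adjusted over the list alone; 0.00486), both at adjusted p = 0.412 with an estimated correlation. The regulatory T programme rose (10 of 12, 1 adjusted over the list alone, limma camera adjusted p = 0.00652, adjusted p = 0.477 with an estimated correlation), with the chemokine receptor Ccr8 at 15.2 against 9.43 CPM. This list did not keep its call with each library left out.

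Ribosomal protein genes fell in T cells (78 of 83 lower, 0 adjusted over the list alone, limma camera adjusted p = 1.47e-09, adjusted p = 0.477 with an estimated correlation). Naive or memory genes fell (11 of 12 lower, 9 adjusted over the list alone, limma camera adjusted p = 1.75e-08, adjusted p = 0.421 with an estimated correlation), with the homing receptor Ccr7 at 83.7 against 126 CPM and S1pr1 at 33.8 against 51.0. The interferon-gamma response (17 of 19 lower, 0 adjusted over the list alone, limma camera adjusted p = 0.00359, adjusted p = 0.471 with an estimated correlation) and the type I interferon response (15 of 20, 3 adjusted over the list alone; 0.00661, adjusted p = 0.421 with an estimated correlation) fell as well. Lists of myeloid genes rose in the T cell class, namely the Trem2-dependent disease-associated list (18 of 24, Cst7 passing over all genes, 5 adjusted over the list alone, limma camera adjusted p = 0.000261, adjusted p = 0.485 with an estimated correlation) and homeostatic microglia genes (13 of 19, 4 adjusted over the list alone; 0.00159, adjusted p = 0.485 with an estimated correlation). The anti-inflammatory or tissue-repair list (11 of 18, 3 adjusted over the list alone, limma camera adjusted p = 0.000248) and the pro-inflammatory list (12 of 18, Cxcl2 passing over all genes, 2 adjusted over the list alone; 0.000996) rose, both at adjusted p = 0.471 with an estimated correlation. Leukocyte-attracting chemokines rose too (6 of 11, 5 rose and 2 fell adjusted over the list alone, limma camera adjusted p = 0.0446, adjusted p = 0.421 with an estimated correlation).

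Markers of other cells moved with these lists in T cells. Neutrophil markers rose (8 of 8, median 1.22, limma camera adjusted p = 1.73e-16), as did plasmacytoid dendritic cell (9 of 9, median 1.05; 3.76e-08), red-cell (4 of 4, median 1.69; 8.21e-06), microglia (10 of 10, median 0.46; 4.41e-05), endothelial (3 of 5; 0.00716) and macrophage markers (7 of 10; 0.00913), whereas fibroblast (4 of 4 lower; 0.00141) and monocyte markers (7 of 10 lower; 0.0231) fell. With an estimated correlation the adjusted p was 0.479 for macrophage markers and 0.278 for the others. Cells with mixed profiles made up 37.7%, 35.7%, 27.4% and 32.8% of the T cell class in Trem2 ASO 1, Trem2 ASO 2, inactive ASO 1 and inactive ASO 2. Without them, an alternative chosen after seeing the data, 15 genes were called, of which 8 were among the 29, with Pclaf, Areg, Trgv2 and Gzmf, and the other calls were lost. This filter removes cells by their neutrophil and macrophage genes, so it decides nothing for such genes and for lists of myeloid genes. The cell cycle (limma camera adjusted p = 2.31e-29) and naive or memory lists (3.42e-08) passed there, whereas the Trem2-dependent (0.0516), homeostatic microglia (0.0656) and pro-inflammatory lists (0.903) did not, and chemokines turned to lower (0.332). Neutrophil markers stayed higher there (limma camera adjusted p = 4.04e-07). The count of 29 called genes became 2 without Trem2 ASO 1, 15 without Trem2 ASO 2, 370 without inactive ASO 1, 919 without inactive ASO 2 and 3 with at least 1000 UMIs per cell. Of the 17 called genes named, only Csta2 and Cstdc4 kept their call with each library left out. Pclaf, Trgv2, Areg and Gzmf lost theirs without Trem2 ASO 1.

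The effects in macrophages and microglia differed for 38 of 15252 genes by an edgeR interaction test, with the effect higher in macrophages for 8 and lower for 30. Ccl24 (log2 difference of effects 4.51 ± 0.45, SE, edgeR adjusted p = 0.00547) and Ccl8 (1.78) were among the former, and Alcam (−1.64 ± 0.13, edgeR adjusted p = 0.00281), Sgms2 (−2.54, edgeR adjusted p = 0.00281) and Slc7a11 (−1.13) among the latter. Sgms2, chosen after its values were seen, is a leading gene of neutrophil cluster 16, and Cstdc4 and Csta2, also among the latter, are abundant in neutrophils. Neutrophil markers rose in microglia (7 of 8, limma camera adjusted p = 3.04e-09, adjusted p = 0.402 with an estimated correlation) and did not pass in macrophages (4 of 8, limma camera adjusted p = 0.55). The count became 8 without Trem2 ASO 1, 62 without Trem2 ASO 2, 409 without inactive ASO 1, 656 without inactive ASO 2 and 5 with at least 1000 UMIs per cell.

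Other named classes gave 10 called genes with edgeR, and DESeq2 called 362 in fibroblast-like cells and 113 in tumour or glial progenitor cells. Fibroblast-like clusters 3, 15 and 19 held Ptprc at 10.6, 11.4 and 10.7 CPM, and the fixed tumour markers do not mark them. Unnamed cluster 9, whose best markers are those of fibroblasts, held 9.04 CPM. Cdkn2a was a leading gene of cluster 3, Hmga2 of cluster 9 and Nras of cluster 19. Whether these clusters hold SB28 cells was left open. Anxa8, an annexin, fell in fibroblast-like cells (2.27 ± 0.445 against 17.9 ± 1.42 CPM, SD, n = 2, edgeR adjusted p = 0.022). The tumour or glial progenitor class was cluster 28 alone, with 26, 29, 52 and 48 cells in Trem2 ASO 1, Trem2 ASO 2, inactive ASO 1 and inactive ASO 2. Its marker score was 3.37, close to 3.12 for astrocyte markers, so its name does not show that it holds tumour cells. In tumour or glial progenitor cells 8 genes rose and 1 fell, among them the lipopolysaccharide-binding protein gene Lbp (160 ± 73.1 against 2.73 ± 2.29 CPM, edgeR adjusted p = 0.0425) and the Wnt inhibitor gene Sfrp1 (79.9 ± 20.8 against 3.29 ± 1.51 CPM). There the transthyretin gene Ttr, on the fixed list of ependymal or choroid markers, was counted in no library labelled Trem2 ASO and at 703 ± 332 CPM under the inactive ASO label. Whether a different makeup of this small class or RNA of other cells gave these calls was not tested. With edgeR 0 genes passed in neutrophils, B cells, NK cells, conventional dendritic cells and oligodendrocytes. An unadjusted p under 0.05 was reached by 743 of 11708, 641 of 8459, 375 of 6757, 305 of 6600 and 350 of 5823 tested genes. Chance alone would give a share of 0.05. DESeq2 called 5, 12, 3, 1 and 6 genes in these classes. Among unnamed clusters, edgeR called 12 genes in cluster 8, 20 in cluster 9 and 1 in cluster 14, where the osteopontin gene Spp1 stood at 399 ± 0.708 against 130 ± 7.74 CPM (edgeR adjusted p = 0.00219). DESeq2 called 12, 405 and 5 genes there, and in cluster 4 it called 31 against 0 with edgeR. In cluster 8, a cluster with few UMIs per cell, Ccl24, Pf4 and Ccl9 rose and the haemoglobin genes Hba-a2, Hbb-bt and Hba-a1 fell. Clusters 22 and 30, led by plasma cell and eosinophil genes, held 0.884% ± 0.0954 against 0.896% ± 1.22 and 0.104% ± 0.0953 against 0.462% ± 0.327 of all cells. Cluster 22 held 0.952% and 0.817% in the libraries labelled Trem2 ASO, 0.0346% in inactive ASO 1 and 1.76% in inactive ASO 2, so the direction turns on which inactive library is left out.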

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

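The test of whether the effect under the Trem2 ASO label differed between macrophages and microglia was planned before the data were examined, and it flagged 38 genes as a difference between groups. The difference of log2 effects, macrophages minus microglia, was −1.64 for Alcam, 4.51 for Ccl24, −1.13 for Slc7a11, 1.04 for Hdac9, −0.98 for Itgax and 1.78 for Ccl8. Alcam had log2 fold changes of −0.26 in macrophages and 1.39 in microglia, and Ccl24 of 4.01 in macrophages and −0.48 in microglia. Sgms2 (−2.54), a leading gene of a neutrophil cluster, was also lower, and neutrophil markers rose in microglia beside these genes (median log2 fold change 1.25, limma camera adjusted p = 3.04e-09, adjusted p = 0.402 with an estimated correlation). No technical explanation was tested for these genes, and a biological difference between the cell types stays open as untested.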

How the results depend on the processing

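With 2 libraries per group, leaving out a library leaves a group with 1 library, which is assumed to vary like the other group, and without an inactive ASO library the spread comes from the close pair labelled Trem2 ASO alone. The alternatives without mixed T cell profiles, with the added free RNA scaling and with the added denominators of shares were chosen after seeing the data, and all others before. Of 1051 values of named genes under alternatives, 776 kept direction and side of the threshold, 112 came to pass, 157 no longer passed and 6 turned. Of 456 list values 325 kept their call, 126 no longer passed and 5 turned, and of 140 shares 134 kept their direction. Over all alternatives the difference of shares ranged in percentage points from 0.157 to 12.5 for macrophages, −8.79 to −0.902 for monocytes, −8.33 to −1.57 for microglia, 3.00 to 5.57 for neutrophils and 0.130 to 2.70 for T cells. With the groups split in 2 other ways 0 genes were called in any class, but 3 splits are too few for a test. The planned free RNA alternative in T cells was not run, since its scaling gave free RNA at up to 110% of UMIs.

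With DESeq2 the counts of called genes were 533 in macrophages, 137 in monocytes, 24 in microglia, 163 in T cells and 502 in other classes, with 68 genes differing between macrophages and microglia, and Trem2 passed in monocytes (log2 fold change 0.56). Of the macrophage genes called by DESeq2, 57.4% were higher, against 73.9% with edgeR. With no filter on low counts they were 669 in monocytes, 146 in microglia, 955 in T cells and 2082 in other classes, with 428 differing, and Trem2 in monocytes passed at 0.56. With at least 1000 UMIs and 500 genes they were 2 in macrophages, 45 in monocytes and 3 in T cells, with 5 differing, 11 lists in microglia, and Ifng in T cells turned to 0.59. With up to 20% mitochondrial UMIs they were 44 in macrophages and 68 in monocytes. With a per-library cell minimum they were 35 in monocytes, 1 in microglia and 7 in T cells, and Foxp3 in T cells turned to −0.04 (−0.0395). With no doublet removal they were 1 in macrophages, 75 in monocytes and 16 in T cells, and Trem2 in monocytes passed at 0.50. At Leiden resolution 0.5 they were 14 in macrophages, 35 in monocytes and 1 in microglia, and Trem2 in monocytes passed at 0.55. At resolution 2.0 they were 216 in macrophages and 0 in monocytes, with 5 lists in macrophages, where the type I interferon (limma camera adjusted p = 0.949), interferon-gamma (0.204) and cell cycle lists (0.0737) turned. Without mixed T cell profiles 15 genes were called in T cells, chemokines turned (limma camera adjusted p = 0.332) and Ifng turned to 0.76. With camera and an estimated correlation, and with fry, 0 lists passed in macrophages, monocytes, microglia and T cells. The cause was not tested.

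With the replicate number as a block the counts were 370 in macrophages, 253 in monocytes, 9 in microglia and 56 in T cells, and Trem2 in monocytes passed at 0.56. Deviations of libraries with the same number correlated at 0.00573, 0.0343, −0.00596 and 0.0336 in macrophages, monocytes, microglia and T cells, so the numbers do not pair the libraries.

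With each library left out, called genes ranged from 15 to 6606 in macrophages, 1 to 2278 in monocytes, 0 to 1386 in microglia and 2 to 919 in T cells, and genes differing between macrophages and microglia from 8 to 656. Lists ranged from 6 to 15 in macrophages, 6 to 15 in monocytes and 7 to 11 in microglia. Lists that did not keep their call with each library left out were interferon-gamma, cell cycle and homeostatic microglia in macrophages. In monocytes they were interferon-gamma, pro-inflammatory, cholesterol biosynthesis and complement, and in microglia glycolysis, homeostatic microglia, tissue repair and complement. In T cells they were regulatory T, interferon-gamma, type I interferon, homeostatic microglia, tissue repair and chemokines. Trem2 ranged from 0.22 to 0.53 in macrophages, 0.55 to 0.58 in monocytes and −0.082 to 0.19 in microglia. Pdcd1 ranged from −0.36 to 0.085 in T cells, Ifng from −1.03 to 0.93 and Gzmb from −0.25 to 0.0046, and the adjusted p of homeostatic microglia genes in microglia from 1.76e-19 to 0.484. Differences of shares ranged in percentage points from −1.56 to 0.00974 for B cells, −0.129 to 0.493 for conventional dendritic cells, −0.170 to 0.0277 for mast cells, and, within T cells, −10.5 to 4.74 for CD8 and −1.21 to 0.398 for gamma-delta T cells. The cause was not tested.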

Other observations

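The test for swapped groups below was chosen only after Trem2 had been seen, and the pattern in T cells was weighed with a definition of mixed profiles also chosen after seeing the data. Trem2 was higher in macrophages of the libraries labelled Trem2 ASO. With the same mix of macrophage clusters in every library its log2 ratio was 0.31, against 0.34 unweighted, which argues against a shift of clusters as the whole cause, and free RNA made up 1.82% of macrophage Trem2 UMIs, against an excess of 26.6%, which argues against free RNA. A swap of the groups cannot be told apart from correct labels, since Trem2 in microglia differed by 0.048 with an SE of 0.12. An effect of the ASO that 3' tag counts do not show, and loss of its effect by the day of collection, stay open as untested.

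Macrophages of inactive ASO 1 stood apart from those of inactive ASO 2. The SD of log2 differences between the inactive ASO libraries was 2.55 times that between the libraries labelled Trem2 ASO, over the 12042 genes with at least 50 UMIs on average, and over all 15133 tested genes the SDs were 0.466 and 0.281. It was 1.98 times with the same mix of macrophage clusters, which argues against the mix as the whole cause. Macrophage UMI totals were 50067971 and 52673128 in the inactive ASO libraries and 52082928 and 47561874 in those labelled Trem2 ASO, so the pair further apart was no shallower, which argues against depth, and thinning to equal totals (2.53 times) could move little and decides nothing. A difference between tumours stays open as untested.

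Neutrophil genes were higher in T cells of the libraries labelled Trem2 ASO. T cells with neutrophil genes held 1.36 to 1.92 times the median UMIs of other T cells in each library, above the minimum set beforehand for droplets joining a T cell with a neutrophil. T cells with more UMIs for another reason would also reach that minimum, so it does not decide for joined droplets. Free RNA cannot be told apart from other causes, since S100a8 and S100a9 rose in B cells by 2.61 times as much as in T cells and fell in NK cells (−0.261 times), the B cell class mixes in plasmacytoid dendritic cell genes, and barcodes of 10 to 100 UMIs held 1.54% and 2.24% of UMIs under the Trem2 ASO label against 0.107% and 0.557%. The planned scaling of free RNA rested on 6 markers for T cells, and 3 for macrophages, of inactive ASO 1. A biological difference between groups in neutrophils, whose share was higher under the Trem2 ASO label, stays open as untested.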
